A study of Mus musculus with 12 samples.

How the data were processed

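The series measured m1A, a methylated form of adenosine in RNA, by RNA immunoprecipitation and sequencing in the caudate putamen of adult male mice whose Tet1 gene carries loxP sites. Per the labels, AAV-EGFP was injected into the control group and AAV-Cre-EGFP into the knockout (KO) group, and tissue was taken afterwards from the injected region. Each genotype had 3 pull-down libraries and 3 input libraries, 12 samples in all. Per the labels' protocols, total RNA was fragmented by heat, most of it was incubated with an m1A antibody, a small part was kept as input, and ribosomal RNA was depleted before random-primed library preparation. The labels do not state that the numbered libraries of a group came from separate animals. The p-values of tests over libraries therefore measure only the spread between these libraries, which may be technical. Those of tests over genes do not measure that spread.

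The submitters' processing notes name cutadapt 2.8, HISAT2 2.1.0, MACS2 2.2.6 and the mouse build GRCm38. Per the file headers, peaks were called with MACS2 separately for each pull-down against its own input, at a q-value limit of 0.01. The headers give an extension setting of 150 bp and modelled fragment lengths of 163 bp (KO 1) to 177 bp (control 2). The 6 peak lists were linked to the pull-down samples, and the inputs entered only through that calling. Per the file headers, control 1 was called with every duplicate tag kept, while in the other 5 libraries the caller kept at most 1 tag per position. For each peak the deposited lists give the authors' pileup, which is a signal (tag coverage at the summit), the −log10 of the p-value and of the q-value, and the fold enrichment over the local background, which is a ratio. These values belong to single peaks and are the authors' own. They were used only to describe, rank or filter peaks within a list. The total and used tags, redundant rates and modelled fragment lengths were also read from the file headers.

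The caller used 459332, 1097292 and 864206 pull-down tags in controls 1, 2 and 3. It used 1235247, 2508102 and 1336328 in KO 1, 2 and 3, so every KO pull-down was deeper than every control pull-down. A peak list holds no read counts outside its peaks, so a region missing from a list was not called at that depth and is not shown to lack m1A. No interval from counting error can be given for a presence or absence call.

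Peaks were placed in genes with a RefSeq table of GRCm38.p6, the same build, which held 49997 genes with their spans but neither exons nor strand nor sequence. A peak counted for every gene whose span held its summit, and a summit in more than 3 genes was left out, which removed 1 peak of control 2 and 1 peak of KO 2. Overlapping genes, antisense genes and introns could not be told apart from exons. The share of peaks in the 5′ UTR or at the start codon had been fixed as a result before the data were examined. It was not computed because the exons were not used here, and the share of summits in protein-coding gene spans took its place. Motif and base composition were not analysed here. Genes of near-identical families, histones and ribosomal proteins among them, share reads with copies and pseudogenes, so which member carried a peak is uncertain.

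Regions were the union of the 6 lists, merged where peaks shared at least 1 bp. A region was called KO-only when it was called in all 3 KO libraries and in no control library, and control-only the other way. Values per library were compared with an exact two-sided permutation test over the 20 assignments of 6 libraries to groups of 3, whose smallest possible p is 0.1, so no such test could pass 0.05. List similarity was the Jaccard index of covered bases, with its within-genotype mean minus its between-genotype mean tested one-sided over the 10 splits. Gene lists were tested by their share of the genes with a peak in each library, and by Fisher's exact test, two-sided, among genes with a peak in all 6 libraries or in 1 genotype alone. The background for Fisher's test was the 6658 genes with a peak in any library, and p-values were adjusted by Benjamini-Hochberg over 25 lists. Genes are not independent replicates. A list was called separated when every KO library lay on the same side of every control library, which chance gives for 10% of lists with 3 libraries against 3.

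The lists were fixed before the data were examined. They covered m1A writers, erasers and readers, the TET and DNA methylation machinery, mitochondrially encoded RNAs, medium spiny neurons, the glutamatergic postsynapse, presynaptic release, GABA signalling and immediate early genes. Housekeeping lists covered cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, translation factors, chaperones, the cytoskeleton, histones, chromatin regulators and abundant non-coding RNAs. Lists of cell types covered oligodendrocytes, astrocytes, microglia, endothelium, choroid plexus, cortical excitatory neurons, striatal interneurons and blood, with an interferon list besides. The mitochondrial list was matched through its chromosome because the table writes those 37 genes without a prefix. Named regions were the first 10 gene-bearing regions of each class (KO-only, control-only, all 6 libraries), ordered by the lowest within-list percentile of −log10 q over the lists that call the region. Tet1, every member of the m1A and TET lists with a peak, and the first 4 recurrent members of each other list were also named. A few genes that the rule names are not reported here. Further members are named only to illustrate counts and were chosen after their values were seen.

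The alternatives fixed beforehand were a −log10 q of at least 5, a fold enrichment of at least 4, chromosomes 1 to 19, X and Y alone, lists of equal length (the best 3004 peaks of each) and peaks within 100 bp joined. The others were a reciprocal overlap of 0.5, calls in at least 2 of 3 libraries, any overlap of a peak with a gene span in place of the summit, each library left out in turn, and a replicate block. Values per 1000000 tags, with and without control 1, the results without control 1 and KO 2, 1 gene per peak, and random draws matched on gene span were added after seeing the data. The code was tested on simulated data, the 6 real lists with regions dealt out without regard to genotype and 200 KO-only regions planted. Over 13772 simulated regions it recovered 200 of the 200, beside 78 KO-only and 32 control-only regions that arose without any genotype effect. No lists were identical. The computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.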

Results

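m1A pull-downs from the caudate putamen, the dorsal striatum of the mouse, were compared between Tet1 KO tissue and control tissue to find transcripts at which loss of TET1 goes with a change in m1A. TET1 is a dioxygenase best known for oxidising methylated cytosine in DNA. The data were 6 peak lists, 3 per genotype, each called against its own input. Controls 1, 2 and 3 had 3179, 3444 and 3004 peaks, and KO 1, 2 and 3 had 3782, 6947 and 3057. Tet1 itself had no peak in any of the 6 lists. A missing peak shows neither the presence nor the absence of the transcript, so the lists give no check of the deletion. Together the lists held 13572 regions, of which 402 were called in all 6 libraries and 9365 (69.0%) in a single library.

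Genes of the synapse and the neuronal cytoskeleton carried m1A peaks in both genotypes. Of the 26 glutamatergic postsynapse genes with any peak, 10 had one in all 6 libraries, against 2.11 expected. They included Dlgap2 and Shank1, postsynaptic scaffold proteins, Homer1, which links glutamate receptors to calcium stores, and Camk2b, a subunit of the calcium/calmodulin-dependent kinase of synaptic plasticity. Dlgap2 had fold enrichments of 8.16 to 24.6 across the libraries, Shank1 7.08 to 13.8, Homer1 3.71 to 14.8 and Camk2b 4.00 to 10.7. Presynaptic release genes followed with 8 of 20 members, against 1.62 expected. Among these were the vesicle SNARE Vamp2 (5.93 to 10.5), the fusion regulator Cplx1 (6.23 to 18.5) and the adhesion receptor Nrxn2 (8.78 to 15.4). Cytoskeletal genes had 11 of 46 members called in all 6 libraries, against 3.73 expected, among them Actg1, Actb, Tuba1a and the spectrin Sptbn4. By Fisher's exact test the adjusted p was 0.000457 for the postsynaptic list, 0.00116 for the presynaptic list and 0.0073 for the cytoskeletal list. Whether transcript abundance accounts for these calls was not tested.

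These 3 lists hold long genes, and genes called in all 6 libraries were longer than others. The median span was 54.1 kb for genes with a peak in all 6 libraries, 29.6 kb for genes with a peak in a single library and 35.5 to 43.0 kb in between, with no steady rise. Against 10000 random draws of genes matched on span, 2.95 postsynaptic, 1.97 presynaptic and 3.92 cytoskeletal members were expected. The one-sided p from these random draws of genes was 0.0002, 0.0009 and 0.001 in that order, without adjustment. The draws were made only for lists that had passed Fisher's exact test, and matched span alone. The presynaptic and cytoskeletal calls ended with peaks of at least 4-fold enrichment (adjusted Fisher's exact p = 0.134 and 0.205). The cytoskeletal call also ended at a −log10 q of at least 5 (0.0721), and the postsynaptic call without control 1 and KO 2 (0.0550).

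The striatum's own projection neurons were represented in the shared set. Adcy5, the main striatal adenylyl cyclase, Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, Gng7, a G protein subunit of dopamine signalling, and Pde10a, a phosphodiesterase rich in medium spiny neurons, had peaks in all 6 libraries. Their fold enrichments ran from 7.33 to 9.98 for Adcy5, 4.24 to 7.87 for Ppp1r1b, 11.6 to 17.5 for Gng7 and 11.9 to 36.1 for Pde10a. In all, 19 of the 24 medium spiny neuron markers had a peak in at least 1 library. KO libraries held 11.7 ± 4.04 (SD, n = 3) of them and control libraries 11 ± 5.57, with an exact permutation p of 1. As a share of genes with a peak they overlapped only through control 1 (0.204%). Controls 2 and 3 had 0.624% and 0.523%, and KO libraries 0.294% to 0.477%. The 4 markers called in all 6 libraries exceeded the 1.54 expected without passing adjustment (Fisher's exact adjusted p = 0.223).

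Of the regions called in all 6 libraries, the first 10 that lie in an annotated gene are given here. Nova1, a neuronal splicing factor, had a region on chromosome 12 from 46707537 to 46708474 with fold enrichments of 15.7 to 37.0. Hexim1, an inhibitor of the elongation kinase P-TEFb, had one on chromosome 11 from 103116253 to 103116654 (12.8 to 24.4). Wasf3, an activator of actin branching, had one on chromosome 5 from 146472723 to 146473318 (13.8 to 36.1). The transcriptional corepressor Ctbp1 had a region on chromosome 5 from 33274632 to 33274920 (19.4 to 28.1). Nbea, a protein of synaptic membrane traffic, had one on chromosome 3 from 56183363 to 56183701 (15.2 to 43.6). The others lay in Sik3, a salt-inducible kinase, with the overlapping Gm46110, in Bcr, Lrrfip2 and Lrrc47, and in the long non-coding RNA gene Gm1604a. Positions are on GRCm38, and whether a summit lies in an exon was not analysed here.

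Ribosomal protein, oxidative phosphorylation and histone genes were called more often in KO tissue. KO libraries had peaks in 17.3 ± 4.51 (SD, n = 3) ribosomal protein genes and control libraries in 7 ± 4.36. For nuclear-encoded oxidative phosphorylation, which makes up the respiratory chain, the numbers were 19.7 ± 3.51 and 10.7 ± 2.52. For histone genes they were 13.3 ± 4.73 and 3.00 ± 2.00. As a share of all genes with a peak, these lists made up 0.594%, 0.683% and 0.497% in KO and 0.289%, 0.441% and 0.122% in control. Every KO library lay above every control library on all 3 lists, by number and by share. Each gave an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow, and over 25 lists an adjusted p of 0.625 for the number and 0.357 for the share.

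Most of these genes were called in at least 1 KO library and in no control. Of 25 histone genes with a peak, 20 were called in KO libraries alone and 1 in a control library alone. The corresponding numbers were 19 and 1 of 29 ribosomal protein genes and 19 and 2 of 36 oxidative phosphorylation genes. Over all 6658 genes with a peak, 2267 were called in KO libraries alone and 1493 in control libraries alone. Rps15, Fau, Rpl41 and Rpl37, components or precursors of the ribosome, were called in all 3 KO libraries and no control, with fold enrichments of 8.04 to 13.8 for Rps15, 5.90 to 12.0 for Fau and 3.06 to 4.50 for Rpl41. The histone variant H2aj (5.29 to 6.24) and the respiratory chain genes Sdha and Ndufv3 showed the same pattern. Rpl13a, Rps16, Cox4i1, Cox6a1, Ndufv1, Atp5a1 and the replication-dependent histone H3c13 had peaks in all 6 libraries, and Atp5d, a subunit of ATP synthase, was called in the 3 controls alone (6.19 to 7.27).

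The 4 ribosomal protein genes among 116 genes with a peak in all KO and no control libraries compared with 0.505 expected, with a Fisher's exact adjusted p of 0.0371. That Fisher's exact call ended without control 1 (adjusted p = 0.176), control 2 (0.269), control 3 (0.141) or KO 1 (0.251), at a −log10 q of at least 5 (0.110) and at a fold enrichment of at least 4 (0.419). It held under the other alternatives, with adjusted p from 0.00277 without KO 2 and 0.00364 with lists of equal length to 0.0419 with 1 gene per peak. Against random draws of genes matched on span the one-sided p from the draws was 0.0039, without adjustment. These draws were made because the list had passed Fisher's exact test on the same calls, so they add no separate support. The same 116 genes held 2 oxidative phosphorylation genes against 0.627 expected and 1 histone gene against 0.436. Neither passed Fisher's exact test (p = 0.129 and 0.356 before adjustment). Control 1, the shallowest library, had the lowest number on all 3 lists, with 2 ribosomal protein, 8 oxidative phosphorylation and 1 histone genes. Separation was lost for oxidative phosphorylation at a −log10 q of at least 5 and for histones at a fold enrichment of at least 4. Astrocyte markers moved with these lists, with 7.67 ± 0.577 (SD, n = 3) members in KO and 5 ± 1.73 in control (exact permutation p = 0.1 for the number, 0.3 for the share).

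**Figure D1:**
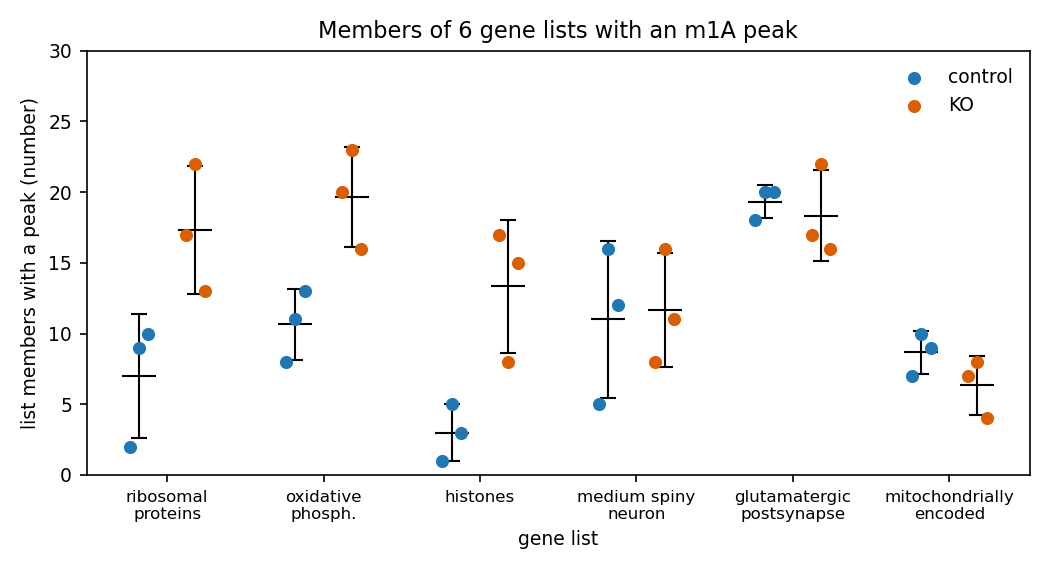
Number of genes with an m1A peak (vertical axis) in each library for 6 gene lists (horizontal axis), with the 3 controls in blue, the 3 KO libraries in orange and the mean ± SD in black. Ribosomal protein genes numbered 2 to 10 in control and 13 to 22 in KO libraries, while medium spiny neuron markers overlapped.

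Another 4 lists separated the genotypes by share alone. GABA signalling genes made up 0.287% of genes with a peak in KO and 0.177% in control, and Slc32a1, the vesicular GABA transporter, was called in all 3 KO libraries and no control. Mitochondrially encoded RNAs made up 0.216% and 0.356%, with ATP6, COX1 and ND1 called in all 6 libraries. Glutamatergic postsynapse genes made up 0.638% and 0.795%, and striatal interneuron markers, of which Sst and Nos1 had a peak, 0.0122% and 0.0411%. The interneuron shares rest on 1 member in each control, 1 in KO 1 and 0 in KO 2 and KO 3. By number the exact permutation p was 0.3, 0.3, 0.8 and 0.4 in that order, and a longer list lowers a share where the number is level. In total 7 of 25 lists separated by share, where chance gives 2.50. The split of KO 1, KO 2 and control 1 against the rest also separated 7. At a −log10 q of at least 5 the GABA and interneuron lists no longer separated. Separation was also lost for interneuron markers at a fold enrichment of at least 4, and for mitochondrial RNAs with any overlap of a peak with a gene span. With lists of equal length 4 separated: the ribosomal protein, oxidative phosphorylation, histone and astrocyte lists, all higher in KO.

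KO-only regions numbered 192. The first-ranked of those in an annotated gene lay on chromosome 18 from 74778484 to 74778716, over the small RNA gene Gm23119 and the non-coding Gm41774, with fold enrichments of 7.45 to 11.1. Others lay in Ulk1, the kinase that starts autophagy (chromosome 5, 110809807 to 110810004, 7.42 to 14.7), and in Ddit4, a stress-induced inhibitor of mTORC1 (chromosome 10, 59949883 to 59950110, 6.46 to 9.81). Hspbp1, a cochaperone of Hsp70, had a region on chromosome 7 from 4669439 to 4669741 (10.5 to 21.7). Sorcs2, a sorting receptor of neurons, had one on chromosome 5 from 36393279 to 36393637 (11.2 to 15.9), and Csmd1, a large membrane protein of the complement-control family, on chromosome 8 from 17265720 to 17265975 (12.6 to 35.4). Dctn1, a subunit of the dynein adaptor dynactin, Washc2 with the overlapping Gm52873, and Tmem260 were also among the first 10.

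Control-only regions numbered 108, fewer than in KO. The first was on chromosome 16 from 57391251 to 57391715 within Filip1l and Cmss1, with fold enrichments of 43.9 to 162. Celf2, a regulator of splicing and mRNA stability, had a region on chromosome 2 from 7076177 to 7076387 (3.40 to 7.21). Meg3, an imprinted long non-coding RNA that overlaps the span of Rtl1, had one on chromosome 12 from 109566588 to 109566913 (5.72 to 7.56), while the Meg3 gene had peaks elsewhere in all 6 libraries. Neuronal genes were Ngef, a guanine nucleotide exchange factor (chromosome 1, 87510029 to 87510339, 7.50 to 8.59), and Ncdn, neurochondrin (chromosome 4, 126753135 to 126753374, 8.54 to 9.19). Laptm5, a lysosomal protein of immune cells, Jarid2, a partner of the Polycomb complex, Tlcd4, Gm19951 and the 18S ribosomal RNA-related pseudogene Rn18s-rs5 completed the 10. The regions in Filip1l and Cmss1, Jarid2 and Rn18s-rs5 are at loci on a list of 13 that can collect ribosomal RNA reads, drawn up after these regions were seen.

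The excess of KO-only over control-only regions depended on the setting. It held at a −log10 q of at least 5 (177 against 95) and at a fold enrichment of at least 4 (174 against 103). It did not hold with lists of equal length or without control 1 and KO 2, neither of which makes depth equal. With lists of equal length, 117 regions were KO-only and 118 control-only. Without control 1 and KO 2, 504 regions were called in both remaining KO and neither remaining control library, and 567 the other way. Among the 20 ways to choose 3 of the 6 libraries, the KO set gave the highest count of exclusive regions. Controls 2 and 3 with KO 2 gave 112, above the 108 of the 3 controls.

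**Figure D2:**
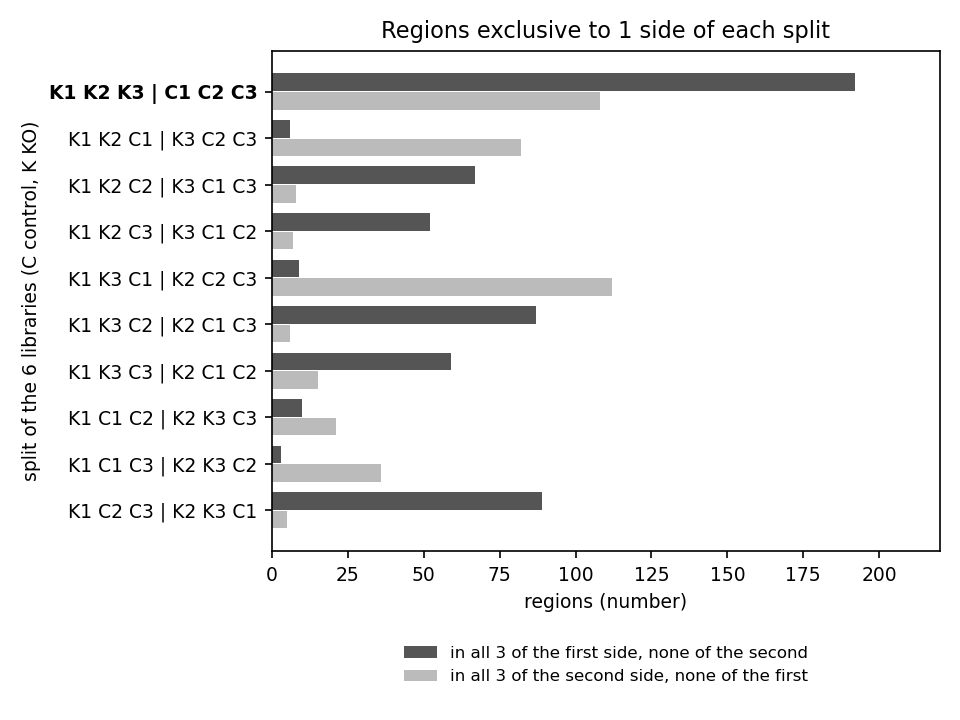
Number of regions (horizontal axis) called in all 3 libraries of a side and in none of the other, for each of the 10 splits of the 6 libraries (vertical axis; C control, K KO, the genotype split in bold). The genotype split gave 192 and 108 regions, 300 together, and the next highest split 121 together.

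Lists of the same genotype overlapped more on average than lists of different genotypes, though not in every pair. The mean Jaccard index was 0.246 within and 0.193 between genotypes, a difference of 0.0534 with a one-sided exact permutation p of 0.1, the smallest possible, and the highest of the other 9 splits gave 0.0250. Controls 2 and 3 shared most (0.444), followed by KO 1 and KO 3 (0.366), and these 4 libraries gave 0.261 to 0.286 between genotypes. Control 1 reached 0.160 and 0.168 with the other controls, and 0.0685 to 0.125 with KO libraries. KO 2 reached 0.180 with KO 1 and 0.159 with KO 3, beside 0.175 with control 2 and 0.153 with control 3. In control 1, 2123 regions (67.4%) were called in that library alone, and 72.4% of all its peaks were exactly as long as the modelled fragment, against at most 16.05% of those of any other library. In KO 2, with the most tags, 4468 regions (64.8%) were its own.

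The number of peaks, the covered length and the genes with a peak did not separate the genotypes. KO libraries had 4595 ± 2069 peaks (SD, n = 3) and control libraries 3209 ± 222, a ratio of 1.43 with an exact permutation p of 0.3. Covered length was 1170 ± 571 kb and 826 ± 170 kb (exact permutation p = 0.5, n = 3), and genes with a peak 2910 ± 718 and 2436 ± 134.4 (exact permutation p = 0.3, n = 3). KO 2 set the difference in peaks, which was 1386 with it and 210.5 without it. Without it the differences in covered length and genes were 17.9 kb and 77.5 genes. Per 1000000 tags used, KO libraries had fewer peaks, 2706 ± 391 against 4512 ± 2093 (exact permutation p = 0.1, n = 3), so the direction depends on how depth is treated. Most of that difference came from control 1, since without it −1805 shrank to −601.

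**Figure D3:**
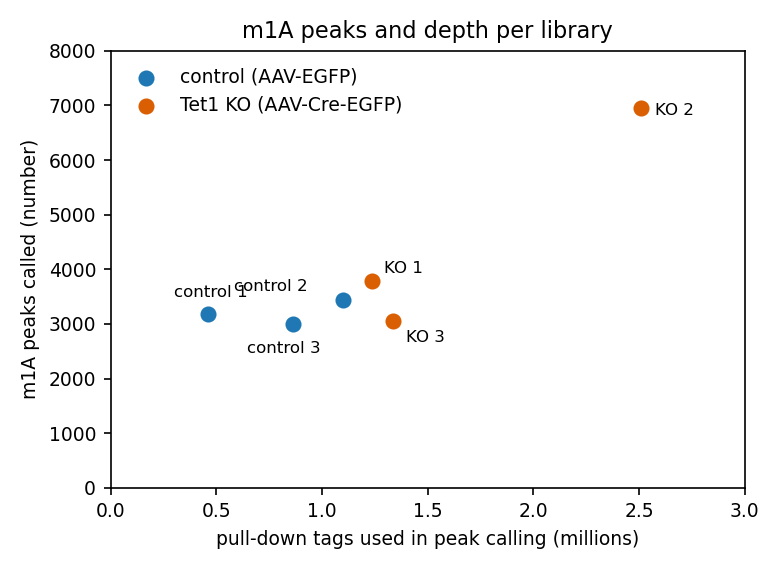
Number of m1A peaks (vertical axis) against pull-down tags used by the peak caller in units of 1000000 (horizontal axis), 1 point per library, controls in blue and KO in orange. KO 2, with 2508102 tags, had 6947 peaks, and the other 5 libraries lay between 3004 and 3782.

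Summits in protein-coding gene spans made up 86.7 ± 0.528% (SD, n = 3) of KO peaks and 89.6 ± 2.06% of control peaks. Every KO library lay below every control library, with an exact permutation p of 0.1 and an adjusted p of 0.333 over the 5 gene classes. Summits in no annotated gene were 8.71 ± 0.573% and 6.15 ± 1.84% (exact permutation p = 0.2, n = 3), and those in long non-coding RNA genes 3.16 ± 0.533% and 2.54 ± 0.219% (exact permutation p = 0.2, n = 3). Malat1, Meg3, the signal recognition particle RNA genes Rn7s1 and Rn7s2 and the small nuclear Rn7sk were called in all 6 libraries. The list of abundant non-coding RNAs held 13.3 ± 0.577 members in KO and 13.0 ± 2.65 in control (exact permutation p = 1, n = 3).

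Of the m1A machinery, 6 of 16 genes had a peak, 3.00 ± 1.00 per library in each genotype. Ythdf3, a cytoplasmic reader protein of methylated RNA, was called in the 3 controls and no KO library, with fold enrichments of 4.40, 7.62 and 7.18. Trmt10b, a tRNA methyltransferase, was called in all 6 (5.41 to 12.0). The m1A demethylase Alkbh3 was called in 2 libraries of each genotype, Fto in 2 KO and 1 control, and Alkbh7 and Ythdc1 in 1 KO library each. Of the TET and DNA methylation list, 7 of 15 genes had a peak, 3.67 ± 0.577 in KO and 2.67 ± 1.15 in control (exact permutation p = 0.4, n = 3). Dnmt3a, a de novo DNA methyltransferase, was called in all 6 libraries (5.16 to 11.2) and the methyl-binding family member Mbd3 in 3 KO and 1 control. Mbd1 was called in 2 KO and 1 control libraries, Tet3 and Gadd45a in 1 of each genotype, Mbd2 in 1 KO and Dnmt1 in 1 control.

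With all 6 libraries, lists of other processes and cell types overlapped between the genotypes by share. Without control 1, the medium spiny neuron, presynaptic, cytoskeletal, oligodendrocyte and interferon lists were lower by share in every KO library. Chance separates 20% of lists in that setting. Immediate early genes numbered 5 ± 2.00 in KO and 5.33 ± 1.53 in control (exact permutation p = 1, n = 3), with Egr1 and Jund, activity-dependent transcription factors, called in all 6 libraries. Translation factors numbered 12.7 ± 3.51 and 9.67 ± 4.93, with Eif4h, a helper of the initiation helicase, called in the 3 KO libraries alone. Chaperones numbered 13.7 ± 2.31 and 9.67 ± 3.21, with Hspa5, the chaperone of the endoplasmic reticulum, in the 3 KO libraries alone and Dnajc3 in all 6. Chromatin regulators numbered 15.7 ± 2.89 and 12.3 ± 3.79, with Chd3, Chd4 and Arid1b in all 6 libraries and Chd9 in the KO libraries alone. The exact permutation p was 0.6, 0.3 and 0.6 for these 3 lists (n = 3). Cytoskeletal genes numbered 27.7 ± 4.62 and 25.3 ± 4.62, and presynaptic genes 16.3 ± 4.04 and 15.7 ± 4.93 (exact permutation p = 0.6 and 0.9, n = 3).

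Among glial markers, oligodendrocyte genes numbered 6.33 ± 1.15 in KO and 4.67 ± 3.21 in control (exact permutation p = 0.7, n = 3), with Mbp, myelin basic protein, called in all 6 libraries. The astrocyte genes Clu and Apoe were called in all 6 and Glul, glutamine synthetase, in the 3 KO libraries alone. Microglia markers numbered 2.33 ± 2.52 and 0.667 ± 1.15, endothelial markers averaged 1.00 in both, choroid plexus markers 0.667 ± 0.577 and 0.333 ± 0.577, and blood markers 0.667 ± 1.15 in both. Interferon and antigen presentation genes numbered 2 in every KO library and 3.00 ± 1.00 in control, with the class I antigen gene H2-D1 in all 6 libraries. Cortical excitatory markers numbered 3.00 ± 1.00 and 3.33 ± 0.577. No exact permutation p for these 6 lists was under 0.4 by number or under 0.2 by share (n = 3).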

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

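The tests without control 1 and KO 2, on KO depth, on the redundant rate, on other cell types, the second on short genes and the count of splits for exclusive regions were chosen after the result was seen. The file headers hold a measure that no comparison used, the share of tags that repeat a position. It was higher in KO than in control libraries, in the pull-downs (lowest KO rate 0.43, highest control rate 0.34) and in the inputs (0.42 and 0.36). Control 1 has no such rate because its duplicates were kept.

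Regions exclusive to a genotype numbered 300, and the highest of the other splits gave 121. The genotype split was the 1 of 10 with so many, and 10 splits are too few for a share under 0.05. The excess of KO-only regions over control-only ones may come from the 2 libraries that stand apart, since without control 1 and KO 2 the KO-only count was 504 against 567, or from list length, since lists of equal length gave 117 against 118. Lower depth of the KO pull-downs could not be tested as the source of the 567 control-only regions. KO 1 and KO 3 were already known to be deeper than controls 2 and 3. Higher depth went with the KO genotype in every pull-down, so its part in the KO-only calls cannot be told apart from genotype. Library preparation or batch cannot be told apart from genotype, since the redundant rate was 0.47 in both KO 1 and KO 3 and 0.34 in controls 2 and 3, and an effect of Tet1 loss stays open beside it.

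Ribosomal protein, oxidative phosphorylation and histone genes had more peaks in KO lists. Longer KO lists are argued against as the whole cause, since with lists of equal length KO libraries still held 21 more members of these lists (41.3 against 20.3). Every KO library lay above every control, though KO 2 only narrowly, with 30 members against 26 in control 3. Cutting the lists does not remove the higher depth of the KO libraries. A rise of short genes in general is left open by its first test, a KO minus control share 0.467 percentage points higher (exact permutation p = 0.8, n = 3). For genes under 10 kb as a whole, a rise as large as that of the lists is argued against. Without control 1 and KO 2 the KO to control ratio was 0.968 for such genes outside the lists and 1.85 for list members. These lists were picked for their rise in the same libraries. Ribosomal protein members with a peak had a median span of 2.56 kb, and a rise limited to the shortest genes was not tested. Other cell types could contribute, with 2 more members of the microglia, endothelial, choroid plexus and blood lists in KO on average (4.67 against 2.67, exact permutation p = 0.4, n = 3) and astrocyte markers higher in every KO library by number (7.67 against 5, exact permutation p = 0.1, n = 3). Sequencing depth, transcript abundance, library preparation and an effect of Tet1 loss were not tested apart. Of the 10 splits, 2 separated 7 lists by share, the genotype split and that of KO 1, KO 2 and control 1 against the rest, and so few splits allow no share under 0.05.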

How the results depend on the processing

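The overlap within minus between genotypes stayed positive under every alternative run (0.0428 to 0.130), and the share of peaks in protein-coding genes stayed lower in KO on average (differences of −4.10 to −1.91 percentage points), but KO and control libraries no longer separated at a −log10 q of at least 5 (exact permutation p = 0.2, n = 3) or with lists of equal length (exact permutation p = 0.4, n = 3). The difference in peaks was positive under every alternative except per 1000000 tags. At a fold enrichment of at least 4 the control-only region of Celf2 lost a control call. Shallow pull-downs, 459332 tags in control 1, limit what a missing peak can show.

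Per 1000000 tags, added after seeing the data, the KO minus control difference turned to −1805 peaks, −412 kb and −1639 genes. Without control 1, added later, these shrank to −601, −257 and −695. Without control 1 and KO 2, also added, covered length turned to −72.2 kb, exclusive regions were 504 for KO and 567 for control, where 4 libraries set a laxer rule, and 13 lists separated, where chance gives 8.33. With lists of equal length the difference in genes turned to −153, KO-only regions fell to 117 and 4 lists separated. Requiring 2 of 3 libraries gave 903 KO-only and 479 control-only regions, as the laxer rule must. At a fold enrichment of at least 4, 1 list was over-represented among genes called in all 6 libraries, against 3. The cause was not tested where none is given.

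Leaving out each library in turn gave differences of 210.5 to 2156 peaks, 17.9 to 547 kb and 77.5 to 777 genes, each lowest without KO 2 and highest without KO 3. KO-only regions ran from 200 to 487 (290 without control 2, 330 without KO 1, 472 without KO 3, 487 without KO 2). Control-only regions ran from 1.3e+02 (2 digits) without KO 1 to 413 without control 1, the only library whose removal moved that count over 1.5-fold. Leaving out a library loosens the rule for exclusive regions, so a rise over the 192 and 108 of all 6 libraries was built in. Lists separated ran from 7 to 12, highest without control 1, where chance gives 5 with 2 libraries against 3, and lists over-represented from 3 to 4.

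The numbers shared by libraries of different genotypes did not pair them: deviations of same-numbered libraries correlated at −0.0249, −0.0192 and −0.0111. With the replicate block the difference in peaks was 1386 (exact sign-flip p = 0.25, the smallest possible) and the overlap difference 0.0513. All 3 pairs agreed in direction for 9 lists, where chance gives 6.25.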

Other observations

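The markers called in every library included 2 of the cortical excitatory neuron list, against 0.487 expected (Fisher's exact adjusted p = 0.247). Slc17a7, the vesicular glutamate transporter of cortical neurons, had a peak in all 6 libraries with fold enrichments of 3.45 to 10.4, and so did Nrgn, a calmodulin-binding postsynaptic protein that striatal neurons also express (5.71 to 9.84). Among other cortical markers, Cux1 was called in 3 libraries, and Neurod2 and Tbr1 in 1 control library each. Among mitochondrial transcripts, ND1 had fold enrichments of 13.5 to 17.2 in the controls and 4.84 to 7.05 in the KO libraries, each the authors' value within its own list and so no measure of change. Eef2k, the kinase of elongation factor eEF2, was called in all 6 libraries as the only translation factor list member to be so.

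Some control-only regions lay at loci that can collect ribosomal RNA reads. From a list of 13 such loci, drawn up after the regions were seen, 5 of the 108 control-only regions lay in Filip1l with Cmss1, Jarid2, Rn18s-rs5, Lars2 and Cdk8, and 1 of the 192 KO-only regions lay in Camk1d. No test was made, because the list was not independent of these regions.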
